A study of Mus musculus with 6 samples.

How the data were processed

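RNA from the duodenum of 3 wild-type and 3 VDR-null mice was hybridised, per the labels, to Affymetrix Mouse Gene 2.0 ST arrays, which measure each transcript with probes spread over its length. Each group comes from the sample titles and the genotype given in the labels. Sex, diet and the targeted allele are not given in the sources used here.

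The deposited values are log2 signals, 1 per probe set and array, which the authors made with RMA (background correction, quantile normalization between arrays and summary of the probes of a set) in Affymetrix Expression Console, per the submitters' processing notes. No version is named, and whether the 6 arrays were normalized together is not given in the sources used here. That the logarithm is to base 2 follows from RMA and from the range of the values, 1.99 to 13.8. The table held 41345 probe sets. The platform annotation paired 23521 of them with 1 gene symbol, 1814 with several and 16010 with none; only those with 1 symbol were named. Of their gene IDs 23328 were found in the RefSeq gene table for GRCm38.p6, which was used for names and for the order of genes along the chromosome, and no symbol needed an update. For each of the 22180 genes the probe set with the highest mean over the 6 arrays was used. A gene was tested when at least 3 of the 6 arrays lay above the median of all values in the table, 5.17, which left 13174 genes. Of these, 457 had several probe sets past the filter.

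Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are VDR-null minus wild-type on the log2 scale, with the moderated standard error and a 95% confidence interval where given; a fold is 2 to the power of the difference. The median standard deviation within a genotype was 0.15 over the tested genes. The number of arrays limits the precision.

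Before the data were examined, 40 gene lists were fixed from general knowledge of the tissue, covering calcium transport, other transport, digestion and metabolism, the cell types of the mucosa and the wall, neighbouring tissues and dissection effects. Of their 841 members 763 had a probe set with a single symbol. Lists with at least 5 tested members, 37 of them, were tested with limma's camera against all other tested genes (preset correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation and with limma's rotation test fry. Members were also adjusted over the list alone. The rule for named genes was fixed at the same time: Vdr; in each direction the genes past the threshold or, where fewer than 5 passed, the 5 with the largest difference among those with an unadjusted p under 0.01, leaving out predicted genes without a name of their own, olfactory and vomeronasal receptors and small RNAs; every tested calcium gene; of each other list up to 2 members with the smallest p where none passed; and the sex-linked transcripts. The second part of the rule applied in both directions.

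Genes near Vdr were compared with all others by Fisher's exact test. Single values over the arrays were compared by exact permutation tests, two-sided, which for 3 arrays against 3 cannot give a p below 0.1. The procedure was tested on simulated data in 10 runs over 13174 genes with 200 changed genes each, drawn with independent residuals of the observed spread. At an adjusted p under 0.05 it recovered 36.6% of 1.5-fold, 71.6% of 2-fold, 95% of 4-fold and 97.8% of 8-fold changes, with 8.7 false calls per run on average. In separate runs, camera found 50 of 50 lists of 20 random genes shifted by 0.5 log2 units and called 2 of 150 unshifted ones. Residuals were independent there too, while genes of many real lists were correlated. These counts therefore do not say how often camera calls an unshifted list on the real arrays.

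The alternatives fixed beforehand were no filter on dim genes, a looser and a stricter one, a second quantile normalization, centring of each array on its median, cyclic loess, a trend and a robust prior for the spread, array weights, the replicate number as a block, each array left out in turn, the mean of a gene's probe sets, all probe sets whether named or not, other thresholds, and 50 or 200 genes on each side of Vdr. Probe sets without a gene symbol entered only the fit of all probe sets.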

Results

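Gene expression was measured in the duodenum of 10-week-old mice of the C57Bl/6 background, 3 wild-type and 3 lacking the vitamin D receptor (VDR-null), with 1 whole-transcript array per mouse. The comparison asks which transcripts of the proximal small intestine, where most regulated calcium absorption takes place, differ when the receptor is missing. The values were log2 signals with medians between 5.15 and 5.19 on the 6 arrays, and 13174 named genes were bright enough to be tested. Throughout, wild-type and VDR-null are the genotypes as labelled.

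Vdr itself, which encodes the receptor, did not separate the genotypes. Its probe set (17321078) read 10.72, 10.95 and 11.11 in wild-type replicates 1 to 3 and 10.99, 10.86 and 10.85 in the VDR-null replicates, a log2 difference of -0.03 ± 0.12 (SE; 95% confidence interval -0.31 to 0.26; limma adjusted p = 0.944), or 0.07 without wild-type replicate 3. A null allele made by removing part of a gene can leave the rest of its transcript in place. Which part is missing here, and where the probes lie, is not given in the sources used here, so this probe set does not check the labels.

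Genes of the list of calcium transport and its vitamin D targets, not all of which carry calcium, showed no shared shift between the genotypes in the fit without covariates. S100g, which encodes the calcium-binding protein calbindin-D9k, averaged 10.21 ± 1.77 (SD, n = 3) in wild-type and 10.16 ± 0.92 (n = 3) in VDR-null duodenum. It ranged from 8.16 to 11.33 among the wild-type mice and from 9.13 to 10.93 among the VDR-null mice. Its difference was 0.51, 0.41 and 0.46 without wild-type replicate 2, wild-type replicate 3 or VDR-null replicate 3, -0.18 and -0.43 without VDR-null replicate 1 or 2, -1.07 without wild-type replicate 1 and -1.20 without both replicate 1 arrays, and -1.53 and -0.81 with the brush border or the smooth muscle mean as a covariate, with a limma adjusted p above 0.8 in each. Atp2b1, the plasma membrane calcium pump, differed by 0.13 ± 0.36 (SE), and Slc37a2, a sugar phosphate exchanger, by 0.38 ± 0.64. The sodium-calcium exchanger Slc8a1 differed by -0.26 ± 0.13, and the claudins Cldn2 by -0.21 ± 0.20, Cldn12 by -0.03 ± 0.11 and Cldn15 by 0.24 ± 0.16. Pth1r differed by -0.08 ± 0.09, Rxra by 0.15 ± 0.14 and Cacna1d by -0.15 ± 0.18. Of the 10 tested members of the calcium list, 4 were higher and 6 lower, and none passed the limma threshold over all genes or adjusted over the list alone. The list's mean difference was 0.01 and its median -0.04. camera gave an adjusted p of 0.943, and 0.976 with an estimated correlation. The mean difference was -0.19 without wild-type replicate 1, -0.0090 without VDR-null replicate 1 and -0.09 without VDR-null replicate 2, and 0.11, 0.12 and 0.13 without wild-type replicate 2, wild-type replicate 3 or VDR-null replicate 3. With the brush border mean as a covariate, chosen after the data were seen, it was -0.29 (camera adjusted p = 0.0239).

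Trpv6, the apical calcium channel of enterocytes, was too dim to be tested and is given here because its values were seen to separate. It read 4.59, 5.38 and 5.80 in wild-type and 4.40, 4.57 and 4.58 in VDR-null duodenum, around the median of all values, 5.17. Background limits these signals, so the size of the difference is not given; with no filter on dim genes the limma adjusted p was 0.736. Cyp24a1, the vitamin D 24-hydroxylase, was dim on all 6 arrays, with means of 4.09 ± 0.03 (SD, n = 3) in wild-type and 4.08 ± 0.14 (n = 3) in VDR-null duodenum. Trpv5, Calb1 and Casr were also dim on all 6 arrays.

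**Figure D1:**
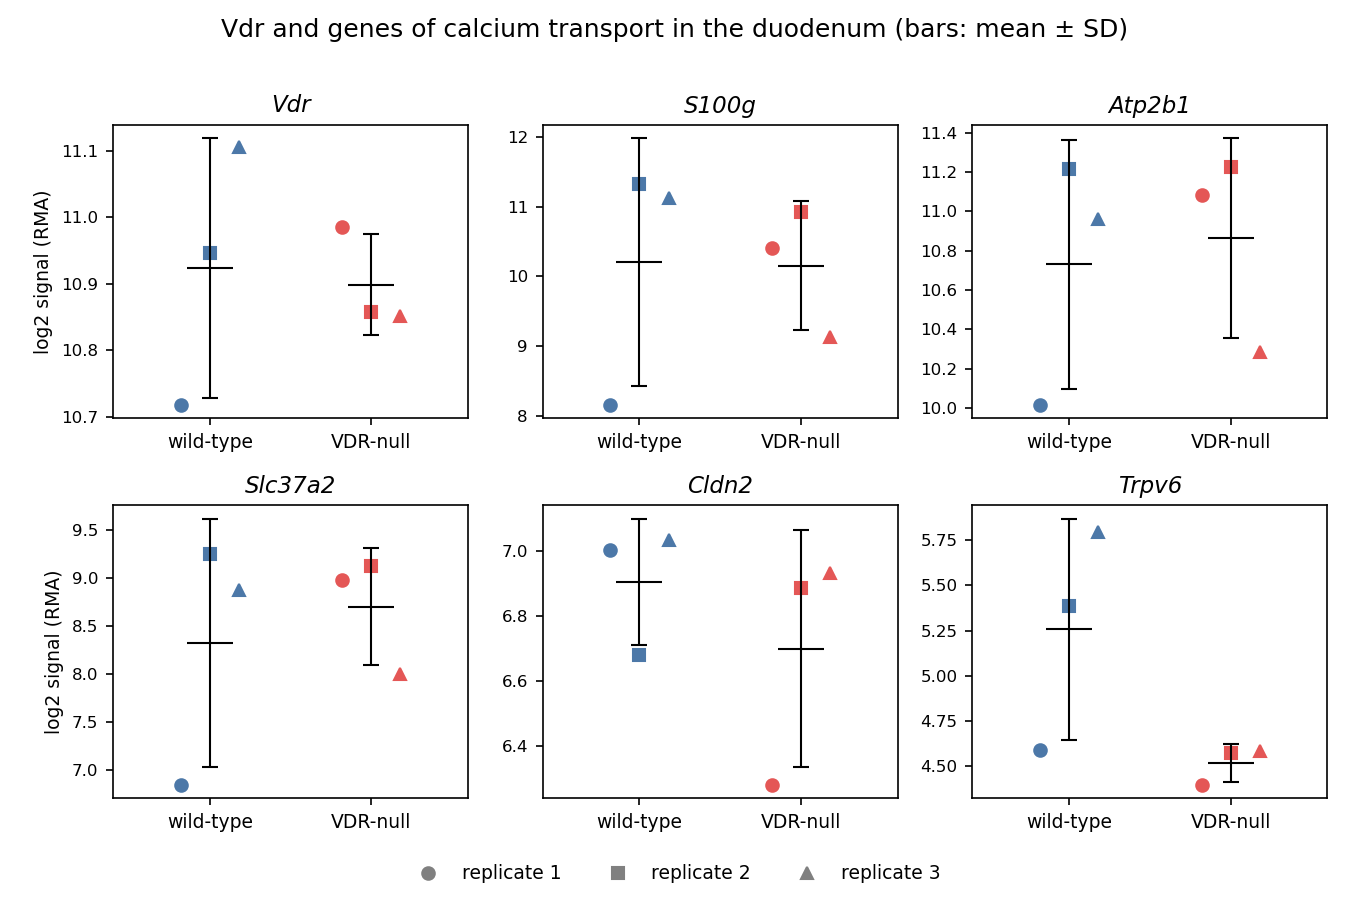
Log2 signal per array (y axis, a separate scale for each gene) of Vdr and 5 members of the list of calcium transport and vitamin D targets. There are 3 wild-type and 3 VDR-null mice, points are arrays, and bars are the mean ± SD. The genotypes overlap in each gene except Trpv6, which is near the median of all values and was not tested.

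Among single genes, the antimicrobial lectin Reg3b and the epithelial tyrosine kinase Ptk6 were the most raised on VDR-null arrays, and the gastrokine Gkn3 and the protease-inhibitor-like gene Wfdc10 the most lowered, among named genes with an unadjusted p under 0.01. None of them passed correction for the genes tested. Reg3b (probe set values 10.73, 10.27 and 8.71 in wild-type; 11.43, 12.04 and 11.64 in VDR-null) was 3.48-fold higher, with a log2 difference of 1.80 ± 0.49 (SE). Ptk6 rested at 5.72 ± 0.09 (SD, n = 3) in wild-type and 7.14 ± 0.55 (n = 3) in VDR-null duodenum, 2.67-fold higher. Shroom1, of a family of actin-binding proteins, was 1.93-fold higher and Hdhd3 1.63-fold. Trim12c, of the tripartite motif family, read 5.66, 5.23 and 5.38 on VDR-null arrays but 4.36, 4.71 and 3.60 in wild-type duodenum, below the filter on dim genes, so the size of its difference is not given. Gkn3 averaged 8.09 ± 0.23 (SD, n = 3) in wild-type and 7.03 ± 0.21 (n = 3) in VDR-null duodenum, 2.09-fold higher in wild-type. Wfdc10 was 1.81-fold higher in wild-type (log2 difference -0.86 ± 0.11, SE), with the smallest unadjusted p of all genes, 9.8e-05 in limma. Sntg2, a syntrophin, differed by -0.59 ± 0.12 (SE), and Muc4, a membrane mucin, and Postn, the matrix protein periostin, were each 1.43-fold higher in wild-type. In all 10 genes the groups of arrays did not overlap, and the adjusted p was 0.683 in each. The genes were picked for a small p and a large difference, which favours separate groups, so the lack of overlap is not independent support.

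**Figure D2:**
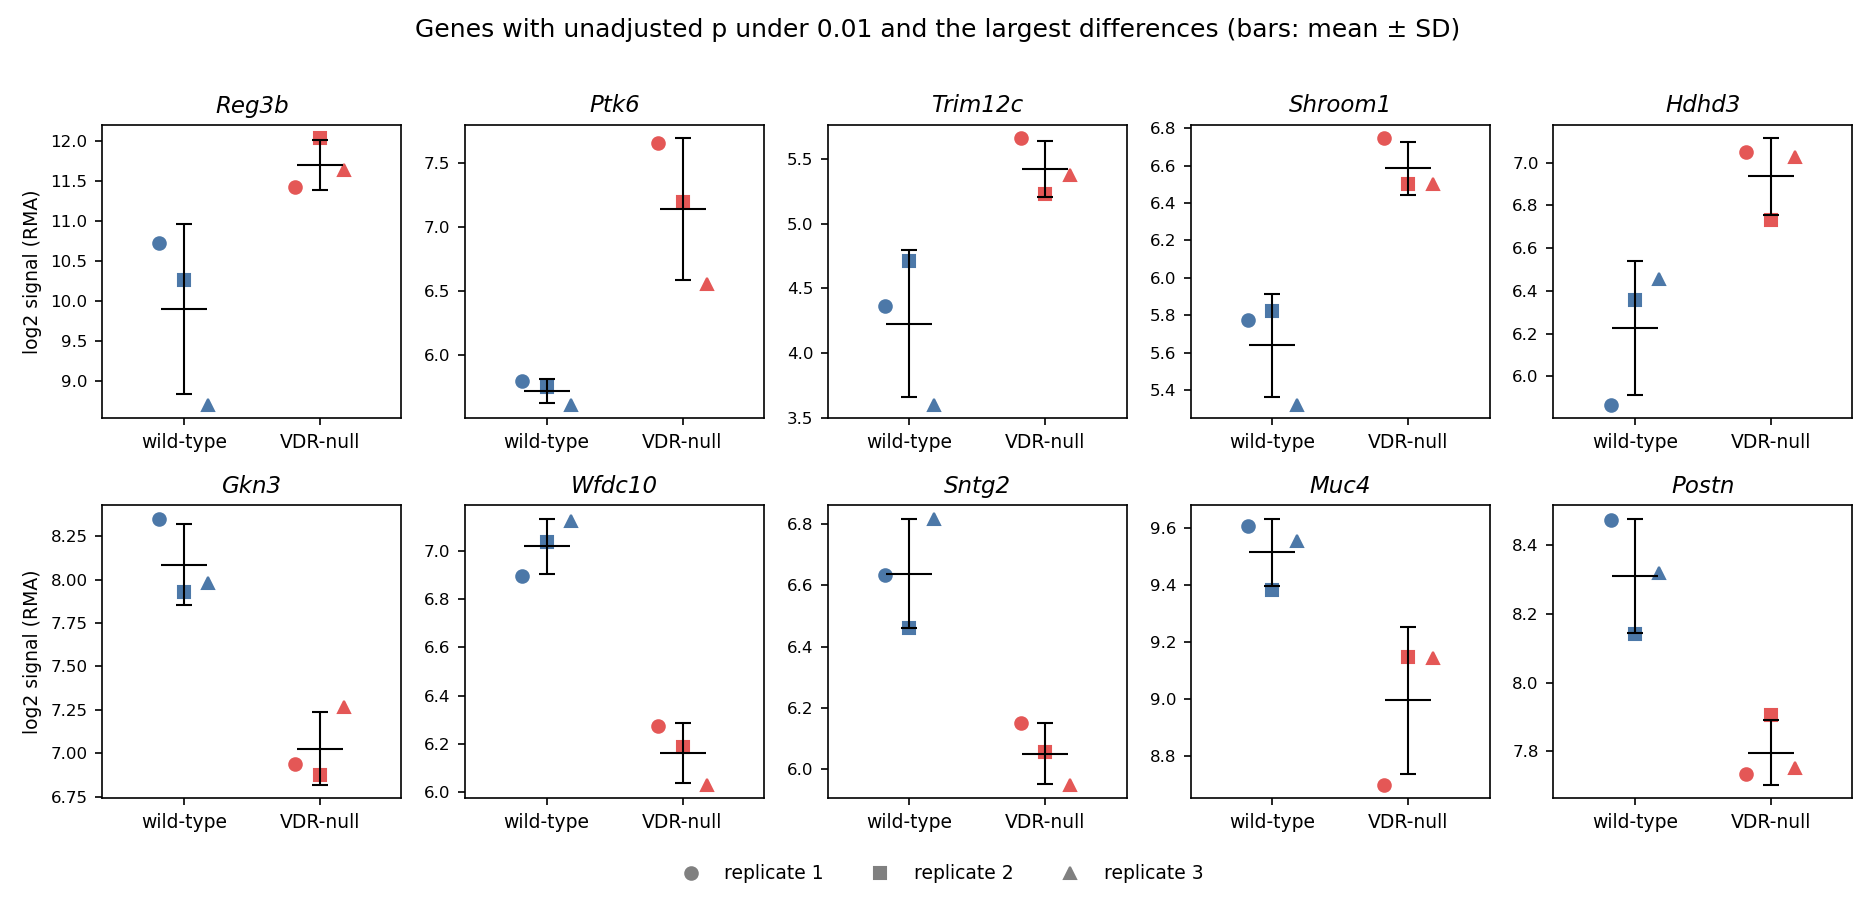
Log2 signal per array (y axis, a separate scale for each gene) of the 5 genes most raised (top) and the 5 most lowered (bottom) on VDR-null arrays among those with an unadjusted p under 0.01; points are arrays, and bars are the mean ± SD. In each gene the 3 VDR-null arrays lie on one side of the 3 wild-type arrays, from a 1.43-fold difference in Postn to a 3.48-fold difference in Reg3b. The genes were picked for a small p, which favours such separation.

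Across all 13174 genes, limma placed 0 past an adjusted p of 0.05, with 689 at an unadjusted p under 0.05, of which 290 were higher and 399 lower in VDR-null duodenum. These were 5.23% of the genes tested. With at least a 1.5-fold difference as well, 66 genes remained, 59 higher and 7 lower. The arrays of the genotypes did not overlap in 1460 genes, or 11.1%, where chance gives 10% for 3 arrays against 3. List members named below were picked for a small p, so a lack of overlap in them is not independent support either. The same test recovered 71.6% of simulated 2-fold changes and 95% of simulated 4-fold changes at this number of arrays and spread. The simulated runs held many changed genes, which makes the adjusted threshold easier to pass, and their residuals were independent. On the real arrays genes within many lists were correlated. The shares therefore do not say how many real 2-fold or 4-fold changes would have been found here.

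Genes of nutrient digestion and absorption were higher on VDR-null arrays as groups, most of all those of carbohydrate and of peptide handling. All 15 tested genes of carbohydrate digestion and transport were higher, by a mean of 1.01 on the log2 scale (camera adjusted p = 2.3e-07). Among them, G6pc, the catalytic subunit of glucose-6-phosphatase, was 3.59-fold higher (log2 difference 1.84, but 1.07 without wild-type replicate 1 and 0.80 without both replicate 1 arrays) and the fructose-pathway kinase Tkfc differed by 0.59 ± 0.24 (SE). Of 21 genes of peptide and amino acid digestion and transport, 19 were higher (mean 0.82; camera adjusted p = 4.0e-09). They include the brush border aminopeptidase Anpep (0.66 ± 0.18) and the amino acid exchanger Slc7a8 (0.54 ± 0.16), whose arrays did not overlap. In lipid absorption and chylomicrons 25 of 26 genes were higher (mean 0.60; camera adjusted p = 7.0e-08), such as Plin3 (0.61 ± 0.29) and Acsl5 (0.63 ± 0.30). All 19 genes of the enterocyte brush border were higher (mean 0.49; camera adjusted p = 7.7e-08), with Anks4b at 0.68 ± 0.25 and ezrin, Ezr, at 0.59 ± 0.25. None of these genes passed the limma threshold. With an estimated correlation the adjusted p was 0.475 for each of these 4 lists.

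The same direction was seen in most lists of transport and of small-molecule metabolism. Genes of drug metabolism and export were higher in 24 of 25 cases (mean 0.66; camera adjusted p = 2.3e-05, and adjusted p = 0.490 with an estimated correlation), with Cyp4f14 at 0.92 ± 0.45 (SE) and the efflux pump Abcb1a at 0.81 ± 0.44. Vitamin A and other vitamin uptake had 17 of 20 genes higher (mean 0.36), with the riboflavin carrier Slc52a3 at 0.34 ± 0.13 and Lrat at 0.34 ± 0.16. Glutathione and oxidant defence had 21 of 25 higher (mean 0.16), with Srxn1 at 0.59 ± 0.29 and Mgst3 at 0.28 ± 0.17. In cholesterol synthesis 16 of 19 genes were higher (mean 0.12), with Hsd17b7 at 0.32 ± 0.12 and Mvk at 0.27 ± 0.12. Phosphate and sulfate transport had 9 of 10 higher (mean 0.45), with Slc26a2 at 0.41 ± 0.18 and Slc9a3r1 at 0.75 ± 0.37 (0.40 without wild-type replicate 1, 0.45 without VDR-null replicate 1 and 0.10 without both). Metal transport (magnesium, zinc, manganese and copper) had 13 of 17 higher (mean 0.17), with the zinc importer Slc39a4 at 0.79 ± 0.31 and Cnnm4 at 0.20 ± 0.09. Iron uptake and handling had 10 of 12 higher (mean 0.30), with the ferroxidase hephaestin, Heph, at 0.86 ± 0.43 and Aco1 at 0.17 ± 0.09. Tight junction genes were higher in 10 of 16 cases (mean 0.13), with Marveld2 at 0.22 ± 0.09 and Cldn23 at 0.31 ± 0.14, and nuclear receptors and coregulators in 17 of 24 (mean 0.12), with Nr1i3 at 0.74 ± 0.37 and Rarg at -0.18 ± 0.10. The camera adjusted p of these 8 lists ran from 0.00068 (vitamin uptake) to 0.0388 (nuclear receptors), and the adjusted p was 0.475 for each with an estimated correlation. Bile acid handling had 7 of 8 genes higher (mean 0.28; camera adjusted p = 0.0423, and adjusted p = 0.501 with an estimated correlation), with the sterol hydroxylase Cyp27a1 1.62-fold higher and Abcc3 at 0.36 ± 0.21. Fatty acid oxidation and ketogenesis had 19 of 23 higher (mean 0.14; camera adjusted p = 0.0224, and adjusted p = 0.647 with an estimated correlation), with Acadm at 0.20 ± 0.12 and Acot1 at -0.30 ± 0.16.

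These absorptive lists moved with single arrays. Relative to the mean of the 6 arrays, wild-type replicate 1 lay at -1.75 in carbohydrate genes and at -0.77 in brush border genes, and VDR-null replicate 1 at 1.11 and 0.61. The other 4 arrays lay between -0.17 and 0.57 in carbohydrate genes and between -0.12 and 0.24 in brush border genes. The first principal component, which carried 62.2% of the variance, had these arrays, 1 of each genotype, at its ends. Whether the genotypes differ along it cannot be decided (exact permutation p = 0.3, two-sided; 3 arrays against 3 cannot go below 0.1). Without wild-type replicate 1 the mean differences were 0.39 for carbohydrate, 0.41 for peptide, 0.21 for lipid and 0.22 for brush border genes, each still past the camera threshold. Without both replicate 1 arrays they were 0.08, 0.13, -0.017 and 0.04, and of the 4 lists only peptide handling stayed past it (camera adjusted p = 0.0060). Without wild-type replicate 1 alone they were 0.02 for drug metabolism, 0.12 for vitamin uptake, 0.05 for oxidant defence, 0.11 for phosphate and sulfate, 0.06 for metal transport, 0.08 for iron, 0.09 for tight junction, 0.04 for nuclear receptors, 0.08 for bile acids and -0.03 for fatty acid oxidation, none of them past it. Cholesterol synthesis kept its call, with a mean of 0.14, but lost it without wild-type replicate 3 (0.06). Without VDR-null replicate 1 the calls of phosphate and sulfate (0.29), iron (0.19), tight junction (0.06), bile acids (0.20), fatty acid oxidation (0.08), cholesterol synthesis (0.04) and nuclear receptors (0.07) were lost. Those of bile acids and fatty acid oxidation were lost without VDR-null replicate 2 too (0.21 and 0.08), and that of bile acids without wild-type replicate 3 (0.30).

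**Figure D3:**
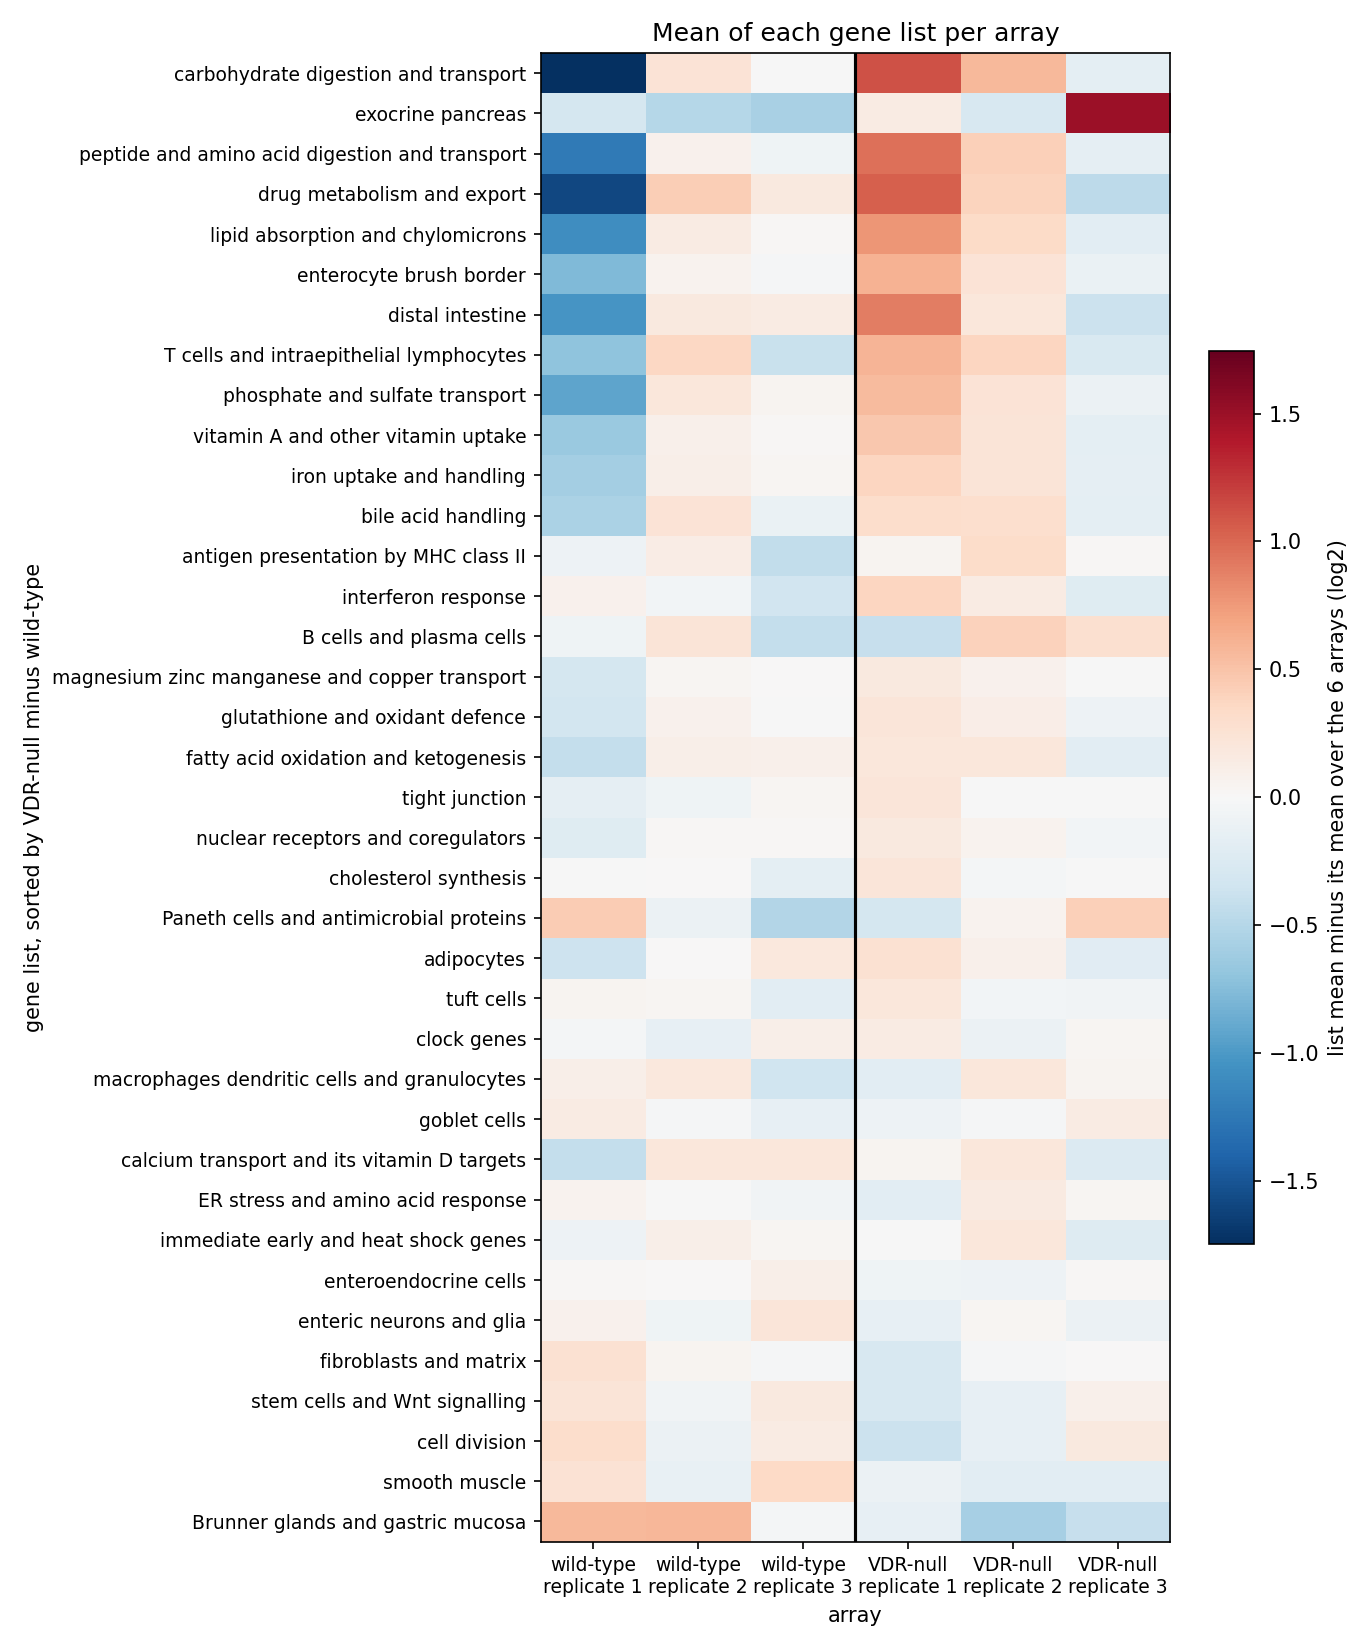
Mean of each of the 37 tested gene lists on each array, minus its mean over the 6 arrays (colour scale, log2 units), with the 3 wild-type arrays left of the line and the 3 VDR-null arrays right of it; lists are sorted by the difference between the genotypes. The absorptive lists are lowest on wild-type replicate 1 (-1.75 for carbohydrate genes) and highest on VDR-null replicate 1 (1.11), and the exocrine pancreas list is highest on VDR-null replicate 3 (1.49).

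Genes of the dividing crypt compartment were lower on VDR-null arrays as groups. All 36 tested genes of cell division were lower, by a mean of -0.24 (camera adjusted p = 2.0e-06, and adjusted p = 0.502 with an estimated correlation), with Tyms at -0.34 ± 0.13 (SE) and the proliferation marker Mki67 at -0.42 ± 0.17. Stem cell and Wnt signalling genes were lower in 18 of 21 cases (mean -0.22; camera adjusted p = 0.00052, and adjusted p = 0.475 with an estimated correlation). They include the stem cell receptor Lgr5, 1.45-fold higher in wild-type and without overlap between the genotypes, and Nkd1 at -0.43 ± 0.16. VDR-null replicate 1 and wild-type replicate 1 were again the lowest and the highest array in both lists. The cell division mean was -0.14 without wild-type replicate 1, -0.11 without VDR-null replicate 1 and -0.0080 without both (camera adjusted p = 0.733). The stem cell mean was -0.17, -0.14 and -0.09 in these fits, with a camera adjusted p of 0.0694 without both.

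Other epithelial cell types showed no shift past the camera threshold. Enteroendocrine genes were lower in 14 of 22 cases (mean -0.09; camera adjusted p = 0.0855), with the transcription factors Nkx2-2 at -0.26 ± 0.08 (SE) and Insm1 at -0.26 ± 0.09. Without wild-type replicate 1 the list had a mean of -0.10 and passed the threshold. Goblet cell genes split 7 higher and 7 lower (mean 0.02, median -0.0047; camera adjusted p = 0.527), with Zg16 at 0.46 ± 0.21 and Clca1 at 0.24 ± 0.15, and had a mean of 0.09, past the threshold, without wild-type replicate 1, of 0.16 with the brush border covariate (camera adjusted p = 0.0020), and of -0.05 and -0.04 without wild-type or VDR-null replicate 3. In the list of Paneth cells and antimicrobial proteins 4 of 16 genes were higher, with a mean of 0.11 and a median of -0.16 (camera adjusted p = 0.943); Reg3b and Reg3a, which is 2.93-fold higher, make up the mean's sign. That list had a mean of 0.36, past the threshold, without wild-type replicate 1, of 0.55 without both replicate 1 arrays and 0.57 with the brush border covariate (camera adjusted p = 8.7e-06 and 1.8e-09), and of -0.11 and -0.07 without wild-type or VDR-null replicate 3. The p-values of these refits rest on the preset correlation of 0.01. In the fit of all arrays without a covariate the estimated correlation was 0.65 for this list and 0.32 for goblet cell genes. Tuft cell genes were higher in 10 of 13 cases (mean 0.06; camera adjusted p = 0.143), with Ltc4s at 0.23 ± 0.09 and Lrmp at 0.17 ± 0.16 (0.03 without VDR-null replicate 1). Their mean was 0.10, past the threshold, without VDR-null replicate 2, and -0.01 and -0.02 without wild-type replicate 3 or VDR-null replicate 1. Genes typical of the distal intestine were higher in 7 of 10 cases (mean 0.48; camera adjusted p = 0.0863), with Ckmt1 at 0.55 ± 0.23 and Clec2h at 1.03 ± 0.53, and passed the threshold without wild-type or VDR-null replicate 2 (means 0.68 and 0.50). Most of that difference rests on the replicate 1 arrays: the mean was 0.09 without wild-type replicate 1 (camera adjusted p = 0.378) and 0.16 without VDR-null replicate 1 (0.596).

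Immune genes were higher on VDR-null arrays in the lists of T cells, interferon response and antigen presentation. T cell and intraepithelial lymphocyte genes were higher in 16 of 18 cases (mean 0.47; camera adjusted p = 0.00020), with perforin, Prf1, at 0.29 ± 0.13 (SE) and Cd3g at 0.77 ± 0.38. Interferon response genes were higher in 28 of 34 cases (mean 0.21; camera adjusted p = 0.00042), with the nucleic acid sensor Zbp1 at 0.68 ± 0.25 and Irf9 at 0.34 ± 0.14. For antigen presentation by MHC class II, 9 of 10 genes were higher (mean 0.26; camera adjusted p = 0.00054), with H2-DMb1 at 0.40 ± 0.14 and H2-DMa at 0.51 ± 0.19, neither overlapping between the genotypes. The adjusted p was 0.475 with an estimated correlation for each of these 3 lists, and the interferon call was lost without wild-type replicate 3 (mean 0.09) or VDR-null replicate 1 (0.07). The T cell list lay at -0.70 on wild-type replicate 1 and at 0.60 on VDR-null replicate 1. Its mean difference was 0.24 without the first, 0.29 without the second and 0.06 without both (camera adjusted p = 0.755). The MHC class II mean was 0.11 without wild-type replicate 3 and 0.16 without VDR-null replicate 2, past the threshold in each. B cell and plasma cell genes were higher in 9 of 13 cases (mean 0.19, camera adjusted p = 0.0575). Cd37 was at 0.21 ± 0.11 and Fcrla at 0.56 ± 0.29, but Fcrla averaged 4.99 in wild-type duodenum, below the filter on dim genes (5.17), so background limits its size. The genes of this list passed the threshold without wild-type replicate 2 (mean 0.34) or VDR-null replicate 1 (0.44). Their mean was 0.02 without wild-type replicate 3, 0.03 without VDR-null replicate 2 and 0.09 without VDR-null replicate 3, and 0.35 with the brush border covariate (camera adjusted p = 0.0157). Macrophage, dendritic cell and granulocyte genes split 9 and 9 (mean 0.04; camera adjusted p = 0.482), with Lyz2 at -0.28 ± 0.11 and Cd14 at 0.30 ± 0.13. Their mean was 0.14, past the threshold, without wild-type replicate 2, and -0.12 and -0.05 without wild-type replicate 3 or VDR-null replicate 2. Only 4 mast cell genes and 0 erythroid genes were bright enough, so neither list was tested.

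Genes of the muscle wall and of connective tissue were lower on VDR-null arrays. Smooth muscle genes were lower in 18 of 19 cases (mean -0.32; camera adjusted p = 1.5e-08), with Synpo2 at -0.42 ± 0.12 (SE) and Mylk, the myosin light chain kinase, at -0.41 ± 0.12, neither overlapping between the genotypes, though the list means did, with wild-type replicate 2 (9.05) below VDR-null replicate 1 (9.07). Fibroblast and matrix genes were lower in 19 of 22 cases (mean -0.20; camera adjusted p = 0.00042), with Postn at -0.51 ± 0.11 and fibulin-2, Fbln2, at -0.30 ± 0.10. All 13 genes of enteric neurons and glia were lower (mean -0.14; camera adjusted p = 0.0208), with Ncam1 at -0.30 ± 0.15 and Nos1 at -0.19 ± 0.10. For each of these 3 lists the adjusted p was 0.475 with an estimated correlation, and the call of enteric neurons was lost without wild-type or VDR-null replicate 3 (means -0.07 and -0.13). The fibroblast mean was -0.12 without wild-type replicate 1, -0.11 without VDR-null replicate 1 and -0.03 without both (camera adjusted p = 0.464). Adipocyte genes were higher in 4 of 7 cases (mean 0.11; camera adjusted p = 0.723), with Fabp4 at -0.36 ± 0.17 and Lipe at 0.40 ± 0.24, and their mean was -0.04 without wild-type replicate 1.

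Brunner gland and gastric mucosa genes were lower in VDR-null duodenum, and theirs was the only one of the 37 lists with members past the threshold adjusted over the list alone. Of its 7 tested members 6 were lower (mean -0.75; camera adjusted p = 0.00024, and adjusted p = 0.475 with an estimated correlation). The rotation test fry, which asks whether the list's own genes move one way on balance, gave an adjusted p of 0.0223. Gkn3 and pepsinogen C, Pgc (1.37-fold higher in wild-type; log2 difference -0.46 ± 0.10, SE), were the 2 members past the limma threshold adjusted over the list alone; over all genes their adjusted p was 0.683. The list means did not overlap between the genotypes (exact permutation p = 0.1, two-sided, the smallest that 3 arrays against 3 allow).

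Exocrine pancreas genes were higher on VDR-null arrays in 9 of 12 cases (mean 0.91; camera adjusted p = 0.00080, and adjusted p = 0.475 with an estimated correlation). Chymotrypsinogen, Ctrb1, had the largest log2 difference of all tested genes, 2.42 ± 0.89 (SE), and read 8.57, 7.24 and 11.06 on VDR-null replicates 1 to 3 against 7.19, 6.19 and 6.22 in wild-type duodenum. The trypsin inhibitor Spink1 was at 1.75 ± 0.75 but did not follow VDR-null replicate 3, where it read 7.98; it was lowest on wild-type replicate 1 (5.86) and highest on VDR-null replicate 1 (10.15), and its difference was 1.00 without the first of these arrays and 0.49 without both. VDR-null replicate 3 alone lay 1.49 above the mean of the 6 arrays in this list, where the other arrays lay between -0.56 and 0.15. Without it the list mean was 0.39 (camera adjusted p = 0.0286) and Ctrb1 differed by 1.37.

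Lists of processes that can differ with the time or handling of a dissection lay close to 0 on average in the fit without covariates. A list mean near 0 can hide members that move in opposite directions, so it does not show that the dissections were matched in time or handling. Clock genes split 9 higher and 7 lower (mean 0.05; camera adjusted p = 0.414; past the threshold, at 0.12, without VDR-null replicate 2, and -0.0054 without VDR-null replicate 1), with Per1 at -0.28 ± 0.17 (SE) and Cry1 at 0.26 ± 0.16. Immediate early and heat shock genes split 8 and 12 (mean -0.03, camera adjusted p = 0.943), with Fosb at 0.37 ± 0.13 and Egr1 at -0.44 ± 0.19. Fosb averaged 5.11 in wild-type duodenum, below the filter on dim genes, so background limits the size of its difference. Genes of endoplasmic reticulum stress and amino acid response split 11 and 12 (mean 0.0072, median -0.010; camera adjusted p = 0.557; past the threshold, at 0.10, without VDR-null replicate 1), with Trib3 at 0.34 ± 0.17 and Ddit3 at 0.18 ± 0.10. In the covariate fits, chosen after the data were seen, clock genes were at 0.22 with the smooth muscle mean (camera adjusted p = 0.0050). With the brush border mean, immediate early genes were at -0.14 (camera adjusted p = 0.0362) and endoplasmic reticulum stress genes at 0.10 (0.0212).

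In all, camera placed 25 of the 37 tested lists past an adjusted p of 0.05, 19 higher and 6 lower in VDR-null duodenum, and 0 with the correlation between a list's genes estimated from the arrays (smallest adjusted p = 0.475). The estimated correlations of the 25 lists ran from -0.05 to 0.90, with a median of 0.39, against the preset 0.01. fry placed 1 list past the threshold. The list means of the genotypes overlapped in all lists but Brunner gland and exocrine pancreas genes. Of the 72 members named from the lists other than calcium, 35 kept under 2/3 of their difference when 1 array was left out, 21 of them most of all without wild-type replicate 1 and 8 without VDR-null replicate 1. Without wild-type replicate 1, 15 of the 25 calls stayed, and without VDR-null replicate 1, 17. Without both arrays 7 stayed and 8 of the 25 lists turned direction, of which drug metabolism (-0.33; camera adjusted p = 0.0018) and fatty acid oxidation (-0.09; camera adjusted p = 0.0153) passed the threshold in the turned direction. Calls gained in that fit, which was chosen after the data were seen, were those of goblet cells (0.14), Paneth cells (0.55), enteroendocrine cells (-0.08), B cells (0.44), macrophages (0.21), adipocytes (-0.15) and endoplasmic reticulum stress (0.13).

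A targeted allele can carry flanking DNA of another strain, so the 100 annotated genes on each side of Vdr were set against all other genes. Of the 64 tested, limma placed 0 past the adjusted threshold, as among all genes. At an unadjusted p under 0.05 there were 2, or 3.13%, against 5.24% of the other genes (Fisher's exact test, two-sided, p = 0.775). They were Amigo2 (-0.35 ± 0.13, SE) and Tmem106c (0.37 ± 0.09), named after their values were seen.

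Y-linked transcripts were present on all 6 arrays. Kdm5d read between 7.48 and 7.64 in wild-type and 7.74, 7.41 and 6.54 in VDR-null replicates 1 to 3, and Eif2s3y and Uty had their lowest values, 7.14 and 6.78, on VDR-null replicate 3 too. Xist, which is expressed from the inactive X chromosome of females, was dim on every array, between 3.51 and 3.72. With 3 bright members the sex-linked list was too small for a test.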

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

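The fits with a covariate, the fit without both wild-type replicate 1 and VDR-null replicate 1 and the count at an unadjusted p under 0.05 were chosen after the data were seen; the other alternatives were fixed before the data were examined. limma placed 0 genes past an adjusted p of 0.05 under every filter, normalization, prior, weighting, block and left-out array tried, and in the planned fit 0 at an adjusted p under 0.10. Without adjustment it placed 689 at a p under 0.05, 290 higher and 399 lower, and 66 with at least a 1.5-fold difference as well, 59 higher and 7 lower. The smallest adjusted p of a named gene over the alternatives was 0.15, and the 10 genes named for their differences at an unadjusted p under 0.01 kept their direction under each of them in which they were tested; the stricter filter on dim genes tested 4 of them. With 50 or 200 genes on each side of Vdr, in place of 100, 2 of 32 (6.25%) and 3 of 127 (2.36%) had an unadjusted p under 0.05. With 10 splits of 6 arrays a share under 0.05 cannot be reached. The real split gave 0 genes past the threshold and the highest other split 0; at an unadjusted p under 0.05 the counts were 689 and 2910, and for lists 25 and 26. The split with 2910 genes sets wild-type replicates 1 and 3 and VDR-null replicate 3 against the rest. The first principal component separates the same arrays, and this split was picked as the highest. It gave 0 genes past the adjusted threshold, so what lies behind its count stays open. The replicate numbers showed no consistent sign of pairing the arrays: the deviations of same-numbered arrays from their group means correlated at -0.62, 0.19 and -0.26. With 3 pairs this cannot exclude a pairing. With the replicate number as a block there were 0 genes and 26 lists. Sex as a covariate was not run, since all 6 arrays carry Y-linked transcripts. Dim genes such as Trpv6 were not tested, and background limits what their signals can show.

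The number of lists past the camera threshold, 25, was 16 with the stricter filter on dim genes, which tests fewer genes, 12 with the smooth muscle mean as a covariate (9 of the 25 calls kept, 4 turned), 18 with the brush border mean (7 kept, 12 turned), 0 with an estimated correlation and 1 with fry, and from 16 to 28 over the fits that leave arrays out; the other settings gave 21 to 26. The calls of peptide and amino acid digestion, MHC class II presentation, smooth muscle and Brunner gland genes held, in the same direction, in each setting with the preset correlation and no covariate. Fits with a covariate or with arrays left out were tested at the preset correlation only, so their camera p-values carry no check with an estimated correlation.

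With the brush border mean as a covariate the direction turned for Atp2b1 (-0.48), Cldn2 (0.029), Cldn15 (-0.018), Slc37a2 (-0.71), Rxra (-0.054), Cacna1d (0.13) and Mgst3 (-0.0053). It also turned for the lists of calcium transport (-0.29), phosphate (-0.11), iron (-0.083), drug metabolism (-0.44), oxidant defence (-0.046), bile acids (-0.077), lipid absorption (-0.083), fatty acid oxidation (-0.15), carbohydrate (-0.026), vitamin uptake (-0.075), cell division (0.023), T cells (-0.029), distal intestine (-0.29), adipocytes (-0.18) and nuclear receptors (-0.024). Of these, calcium transport (camera adjusted p = 0.0239), drug metabolism (3.4e-08), lipid absorption (0.0197), fatty acid oxidation (0.00054), distal intestine (0.0445) and adipocytes (0.0197) passed the threshold in the turned direction. With the smooth muscle mean it turned for Vdr (0.015), Atp2b1 (-0.21), Cldn12 (0.18), Slc37a2 (-0.29), Abcc3 (-0.049) and Fcrla (-0.00011), and for calcium transport (-0.11), bile acids (-0.029), goblet cells (-0.018), Paneth cells (-0.025), tuft cells (-0.0047), MHC class II (-0.068), B cells (-0.28), T cells (-0.043), macrophages (-0.26), enteric neurons (0.012) and endoplasmic reticulum stress (-0.040), with B cells (camera adjusted p = 0.0230) and macrophages (9.8e-05) past the threshold in the turned direction. Array weights turned S100g (0.040) and Cacna1d (0.027). Cyclic loess turned Cldn12 (0.0010) and immediate early genes (0.0025). A second quantile normalization turned calcium transport (-0.0034), goblet cells (-0.023) and endoplasmic reticulum stress (-0.018), and the stricter filter turned macrophages (-0.010) and endoplasmic reticulum stress (-0.040). The cause was not tested in these cases.

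Over the fits that leave arrays out, the difference changed sign for Vdr (-0.17 to 0.066), S100g (-1.20 to 0.51), Atp2b1 (-0.33 to 0.42), Cldn2 (-0.32 to 0.052), Cldn12 (-0.12 to 0.051), Slc37a2 (-0.50 to 0.84), Rxra (-0.046 to 0.24) and Cacna1d (-0.25 to 0.14). Among lists it did so for calcium transport (-0.21 to 0.13), phosphate (-0.055 to 0.67), iron (-0.032 to 0.45), drug metabolism (-0.33 to 1.04), oxidant defence (-0.018 to 0.24), lipid absorption (-0.017 to 0.85), fatty acid oxidation (-0.095 to 0.27), vitamin uptake (-0.027 to 0.53), goblet cells (-0.048 to 0.14), Paneth cells (-0.11 to 0.55), tuft cells (-0.022 to 0.11), macrophages (-0.12 to 0.21), distal intestine (-0.24 to 0.78), adipocytes (-0.15 to 0.24), clock genes (-0.0087 to 0.12), immediate early genes (-0.13 to 0.080), endoplasmic reticulum stress (-0.072 to 0.13) and nuclear receptors (-0.013 to 0.17).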

Other observations

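The tests in this part were chosen after the result was seen, except those of the endothelial genes and of 8 further acinar genes, whose lists and bounds were written before their results were seen. The 3 Reg3 lectins in the list of Paneth cells and antimicrobial proteins were each higher on VDR-null arrays without passing the limma threshold. Reg3b, Reg3a and Reg3g, secreted antimicrobial proteins of the small intestine, differed by 1.80 ± 0.49 (SE), 1.55 ± 0.48 and 0.73 ± 0.32. Part of this rests on wild-type replicate 3, lowest in Reg3b (8.71) and Reg3g (10.56), and Reg3b differed by 1.20 without it. Reg3a and Reg3g overlapped between the genotypes. Reg3a was lowest on wild-type replicate 1 and highest on VDR-null replicate 1 (7.86). Its difference was 1.21 without wild-type replicate 1 and 0.89 without both replicate 1 arrays. Some enzymes of the enterocyte surface spanned a wide range between single mice: lactase, Lct, read 5.74, 10.15 and 10.07 in wild-type replicates 1 to 3 and 11.69, 10.59 and 9.49 in the VDR-null replicates, and the enteropeptidase gene Tmprss15 read 5.21, 8.22, 8.29, 10.12, 8.92 and 6.89 in the same order.

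The probe set 17284469, which has no gene symbol in the annotation used here, had the smallest p of the unnamed probe sets tested, with 7.46, 9.02 and 8.31 in wild-type and 4.11, 3.77 and 3.77 in VDR-null duodenum. The VDR-null values lie near the lower quartile of all values, 3.84, where background limits the signal, so the size of the difference is not given. Its limma adjusted p was 0.0806 among the 7135 unnamed probe sets tested and 0.230 over all 20925 probe sets.

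Absorptive genes were low on wild-type replicate 1. A larger share of muscle wall RNA stays open. Wild-type replicate 3, with the highest smooth muscle mean of all arrays (9.53), lay 0.74 ± 0.13 (SE over genes) above replicate 1 in the brush border mean. Replicate 1 had a high smooth muscle mean too (9.43), and a single pair of arrays does not decide. A second quantile normalization left the gap to the other wild-type arrays in the brush border mean at -0.77 ± 0.13, against -0.79 before. It cannot decide on array scaling, since RMA had already normalized the values by quantiles and the array medians were alike (5.15 to 5.19). A larger share of crypt against villus RNA stays a candidate explanation: over the 6 arrays the cell division mean ran against the brush border mean (Pearson r = -0.93, exact permutation p = 0.0069, Benjamini-Hochberg p = 0.0139 over 2 relations; Spearman rho = -1, exact permutation p = 0.0028; r = -0.92 without the 2 arrays farthest from the median), while the smooth muscle mean gave r = -0.55 (exact permutation p = 0.310). Both lists had already been seen to have the replicate 1 arrays at opposite ends, so this relation is not independent support. Other lists ran along the same arrays, such as distal intestine (-1.03 on wild-type replicate 1 and 0.89 on VDR-null replicate 1), so it does not single out the crypt share. No biological explanation was tested, since replicate 1 shares its labels with the other wild-type mice.

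Gkn3, Wfdc10 and Pgc were lower on all VDR-null arrays. Less Brunner gland or pyloric tissue in the VDR-null samples stays open. The gland transcripts Muc6 and Tff2 were lower on average as well (-1.47 ± 0.70, SE, and -1.47 ± 0.86). Both spread widely among the wild-type mice: in replicates 1 to 3 Muc6 read 7.91, 7.41 and 5.36 and Tff2 9.83, 9.59 and 6.84. On VDR-null replicate 1 they were 1.14 higher than on wild-type replicate 3, while the 3 genes were lower there (mean -0.80), and a single pair of arrays does not decide. Gkn3 was lower together with the endothelial genes Tek (-0.49 ± 0.10, SE), Flt1 (-0.49 ± 0.12), Ldb2 (-0.45 ± 0.12) and Tspan18 (-0.45 ± 0.11), so less blood vessel RNA may be shared by them. Of 21 other endothelial genes 20 were lower, by a mean of -0.26 ± 0.03 (SE over genes). Their list mean read 8.08, 7.75 and 7.75 in wild-type replicates 1 to 3 and 7.52, 7.56 and 7.74 in the VDR-null replicates, so wild-type replicate 1 carried much of the difference. The camera p was 5.4e-07 at the preset correlation and 0.152 with an estimated correlation, and the exact permutation p was 0.1 for the list mean, so this stays open. An effect of the genotype on these genes stays open too and was not tested separately.

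VDR-null replicate 3 combined high pancreatic and low Y-linked transcripts. Against the other 2 VDR-null arrays, 13 of the 21 measured members of the exocrine pancreas list, dim ones included, lay over 1 log2 unit higher (median of the 21, 1.86). Ctrb1 read 11.06, but among tested members Ctrc lay only 0.14 and Zg16 0.0050 higher and Spink1 1.70 lower. Prss1, Amy2b and Try5 were below the filter on dim genes on all 6 arrays, where background limits the signal, so their differences are not given. Pancreas tissue carried over with the duodenum stays open as their source: 8 acinar genes outside the list had a median difference of 0.40 (range -0.17 to 1.83), with 3 over 0.5, which lies between the bounds of above 0.5 and below 0.2. Dilution by pancreas RNA is argued against for the Y-linked genes, whose mean was -0.94 ± 0.10 (SE over 3 genes) against the other 2 VDR-null arrays, since the smooth muscle mean differed by -0.041 ± 0.059. RNA of a female mouse in this sample cannot be told apart from other causes, since Xist was dim on all 6 arrays and differed by 0.012 from the other 5.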
